A study of Homo sapiens with 6 samples.

How the data were processed

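Cytoplasmic RNA of 6 LNCaP clones was extracted with Trizol, labelled with biotin and hybridised to Affymetrix human Gene ST arrays, 1 array per clone, per the labels' protocols and the design text. The clones fall into 2 groups of 3 by their titles: scrambled hairpin control and MBD2 knockdown. The deposited table holds log2 expression values per array feature, made by the authors with RMA, which corrects background, normalizes arrays to a common distribution and summarises probes. RMA and the R packages oligo and limma are named in the submitters' processing notes, and versions and filters are not given in the sources used here. That the values are on a log2 scale was taken from their range and from RMA. Values were used as deposited, without further normalization.

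The table holds 19712 features. Of these 17334 are paired with 1 gene symbol, 1521 with several and 857 with none listed here. Genes were named only from features with 1 symbol, and 17324 of these matched a gene of the RefSeq table of assembly GRCh38.p14 by gene identifier, with 0 symbols updated. For 469 genes with over 1 feature the feature with the highest mean was kept, which left 16704 genes. The 2378 features with several symbols or none were tested separately: 0 had an adjusted p under 0.05 and 316 an unadjusted p under 0.05. MBD2 has 1 feature. For HLA-DMB, which has 2 features, the other one gave a log2 fold change of -0.29, and for MT2A, which has 3, both others had the same sign. PSG9, the metallothioneins, the protocadherins, the MAGE genes and the GSTA and GSTM genes belong to families with near-identical members, so which member their features measure is uncertain.

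Knockdown was compared with control by lmFit and eBayes of limma 3.58.1 in R 4.3.3, on the log2 scale with no trend and no covariates, and p was adjusted by Benjamini-Hochberg over all genes tested. A gene passed at an adjusted p under 0.05. Log2 fold changes are knockdown minus control. The 95% interval of MBD2 comes from the same fit, and its exact permutation test used all splits of its 6 values. Gene lists were tested with camera at its preset correlation of 0.01, adjusted over the 26 lists with at least 5 measured members, and beside it with camera's estimated correlation and with fry. The 27 lists named 882 members, of which 727 were measured and the others were not analysed here. The list of nuclear-retained and small non-coding RNAs had 3 measured members and was not tested.

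The lists, the tests of genes and lists, the alternatives and the rule for naming genes were fixed before the data were examined, except where the text says otherwise. Tests of explanations in the last part were set up for patterns seen in the data. Their predictions were written before each result, except those named there. The rule names MBD2 and then 12 genes per direction with the largest change among genes that passed and whose groups did not overlap. Where fewer passed, it takes the genes with the smallest unadjusted p in that direction. Since 0 passed, all were named by p, with MBD2 among the 12 lower ones, and are reported as not past the threshold. Of each list up to 4 members that passed are named, or, where none passed, the 2 with the smallest p. Other genes named in the text were chosen after their values were seen. Dim genes were not filtered out. Some named list members, for example KRT15, MAGEA11, HOXA2, STMN2 and IKZF1, had control means under the lower quartile of every array (4.71 at its lowest).

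The fit and the list tests were tested on simulated data with 200 of 16704 genes changed, over 20 draws. Variances were drawn from the distribution that eBayes fitted to the real genes. There 88.9% of genes changed 2-fold and 98.8% of those changed 4-fold were recovered, with the right sign in 100%, and 4.73% of calls were false. These draws take noise as independent between clones, and the shares hold for that setting only. In the real data 63 genes differed at least 2-fold and 0 had an adjusted p under 0.05.

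Alternatives tried were centring each array on its median, repeated quantile normalization, cyclic loess, leaving out the dimmest 30% of genes, eBayes with trend and robust settings, array weights, the replicate number as a block, the mean of all features of a gene, leaving out each array in turn, all features of the table, a 1.5-fold minimum, an adjusted p under 0.1 and a plain equal-variance test. Averaging knockdown clones 2 and 3 as 1 replicate was added after the arrays had been compared. The chance correlation of clones that share controls was simulated in 20 draws of unchanged arrays with the SD of the control clones. Gene order for tests of neighbouring genes came from the same RefSeq table, with 16669 genes ordered, in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Values beyond the 1st and 99th percentile were set to those percentiles in that test.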

Results

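The study profiled cytoplasmic RNA of LNCaP cells on Affymetrix human Gene ST arrays, which measure the transcripts of each gene with many short probes. LNCaP is an androgen-responsive prostate cancer line. The cells carried either a short hairpin RNA against MBD2, a protein that binds methylated CpG dinucleotides and recruits the NuRD repressor complex, or a scrambled hairpin. There were 3 scrambled control clones and 3 MBD2 knockdown clones with 1 array each, and per the design text the replicates are separate stably transfected clones. The median log2 value per array lay between 6.32 and 6.35. The array of knockdown clone 1 had a narrower distribution than the others, with an SD over genes of 2.05 against 2.10 to 2.12. The number of arrays limits the precision of every comparison.

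The only comparison in the design is MBD2 knockdown against scrambled control, which asks which genes change expression when MBD2 is reduced. MBD2 itself (feature 8023382) was lower in 3 of 3 knockdown clones than in any control clone. Its log2 value was 9.06 ± 0.29 in the controls and 7.78 ± 0.08 in the knockdown clones (mean ± SD, n = 3 each), a log2 fold change of -1.28 with a standard error of 0.14. That left 41.2% of the control level, with a 95% confidence interval of 32.6% to 52.0%. Knockdown clones 1, 2 and 3 stood at 7.68, 7.84 and 7.81, so the depth of knockdown in RNA was similar in all 3. MBD2 ranked 4 by p among 16704 genes in limma's moderated test, with an adjusted p of 0.111, and an exact two-sided permutation test of the 6 values gave 0.1, the smallest p that 3 against 3 allows. It passed the threshold without control clone 1 (adjusted p = 0.0179) and without knockdown clone 1 (adjusted p = 0.0498). Without knockdown clone 1 the fit rests on knockdown clones 2 and 3, the most alike of all pairs of clones (SD of their difference 0.185). With both averaged as 1 replicate beside clone 1, MBD2 did not pass, as it did not in the full fit.

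No other gene passed the threshold either, and ATP11A and ZNF487 came nearest to it. Of the 12 genes with the smallest p on the higher side, the largest difference was that of ATP11A, a phospholipid flippase of the plasma membrane, which was 3.49-fold higher in the knockdown clones (log2 fold change 1.80, SE 0.16, adjusted p = 0.0668). CAPN5, a calpain protease, was 2.46-fold higher, and the kinase gene SGK2 was 2.27-fold higher. PDZK1IP1, which codes for a small membrane protein, and HPD, an enzyme of tyrosine breakdown, had log2 fold changes of 1.01 and 0.99. CHST15, a sulfotransferase that acts on chondroitin sulfate, and CD55, an inhibitor of complement on the cell surface, had 0.92 and 0.86. The secreted glycoprotein STC1 had 0.77, REEP6 0.61 and the folate receptor gene FOLR1 0.57. The nuclear receptor gene NR5A2 and the pregnancy-specific glycoprotein gene PSG9 had 0.53 and 0.48. Signals were dim for NR5A2, PSG9 and FOLR1, with control means of 4.14, 4.43 and 4.64, under the lower quartile of every array. HPD, at 4.72, lay close to it. In each of these 12 genes all 3 knockdown clones lay above all 3 controls, and their adjusted p lay between 0.0668 and 0.229. Without knockdown clone 1, ATP11A (adjusted p = 0.036), SGK2, STC1, CAPN5, FOLR1 and CD55 (each 0.0498) passed, and without control clone 1 ATP11A did (0.0491). The first of these fits rests on clones 2 and 3, the most alike pair. With both averaged as 1 replicate no gene passed, but that fit includes clone 1 again. With array weights, which gave knockdown clone 1 a weight of 0.252 and clone 2 one of 3.43, all 12 genes passed.

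On the lower side, EXPH5, an effector of the vesicle-transport protein RAB27, had a log2 fold change of -1.30, and ZC3H12C, of a family of RNA-degrading zinc finger proteins, had -1.26. ST7 had -1.09 and the zinc finger gene ZNF487 had -1.04 (SE 0.10, adjusted p = 0.0668). EXPH5 and ZC3H12C lie near each other in the genome, with 2 measured genes between them. The amino acid transporter SLC36A1 had -0.81 and BEND7 had -0.77. Lower too were RUFY3 (-0.57), GCLM (-0.56), which encodes the modifier subunit of the enzyme that starts glutathione synthesis, and RTKN2 (-0.56). B2M, the light chain of MHC class I, had -0.55, and SFT2D1 had -0.53. All 3 knockdown clones lay below all 3 controls in each of these genes, and EXPH5 differed most between knockdown clones, with log2 values of 7.40 in clone 1, 6.62 in clone 2 and 6.68 in clone 3 against 8.20 in the controls. Without knockdown clone 1, EXPH5 (adjusted p = 0.0034), ZNF487 (0.0232), SLC36A1, ZC3H12C, SFT2D1 and BEND7 (each 0.0498) passed, and ZNF487 also passed after quantile normalization (0.0482) and cyclic loess (0.042). The fit without knockdown clone 1 again rests on the alike clones 2 and 3. With both averaged beside clone 1 none of these genes passed. With array weights all of them passed.

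**Figure D1:**
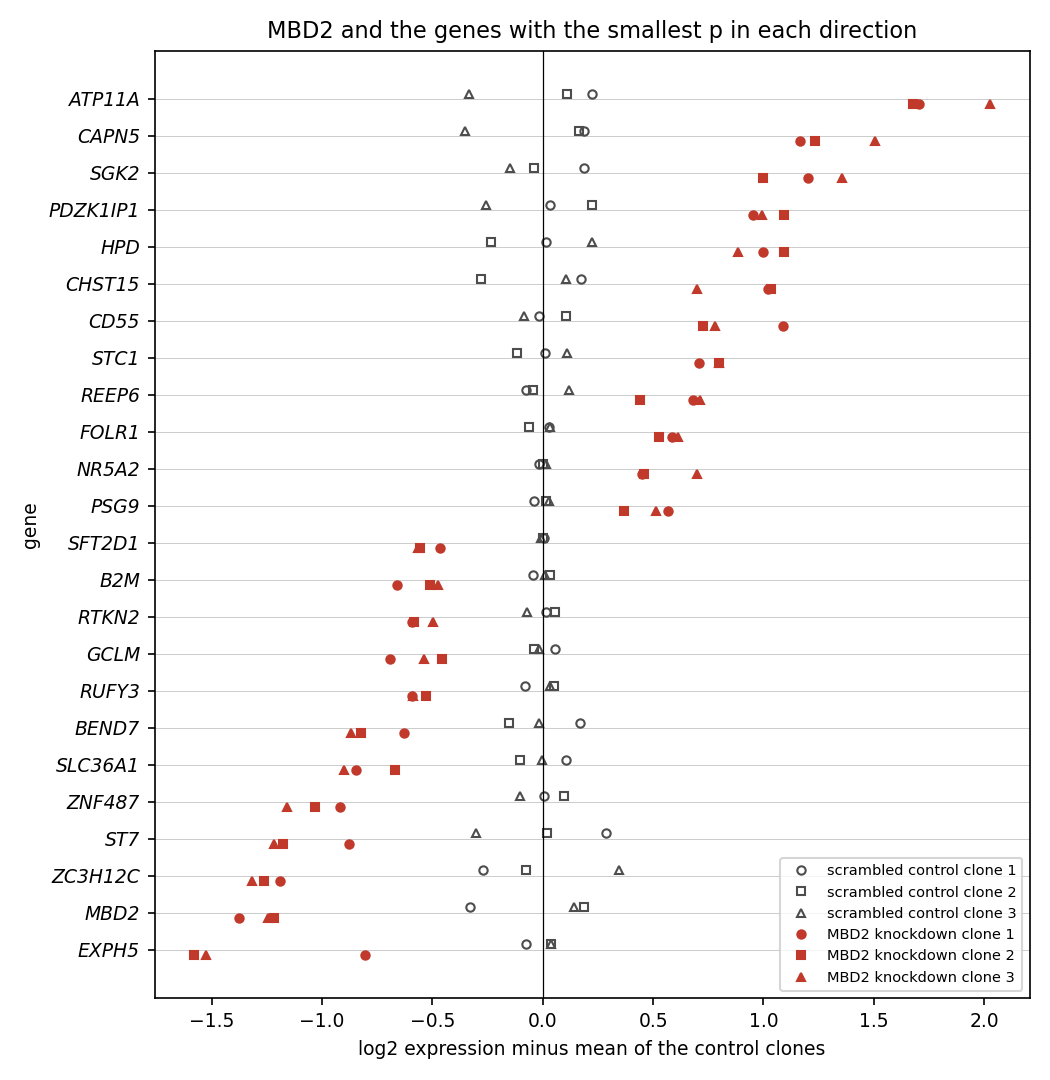
Log2 expression of the 12 higher and 12 lower genes, MBD2 among the lower ones, in each clone, minus the mean of the 3 control clones; open grey symbols are scrambled control clones and filled red symbols are MBD2 knockdown clones. In every gene plotted the knockdown clones lie apart from the controls on one side, and of the genes plotted ATP11A (1.80) and EXPH5 (-1.30) have the largest mean differences.

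Of 16704 genes tested with limma, 0 had an adjusted p under 0.05, and a plain equal-variance test without moderation also gave 0, with 1409 genes at an unadjusted p under 0.05. The smallest adjusted p was 0.0668, shared by ATP11A and ZNF487. At an unadjusted p under 0.05 there were 1568 genes, 657 higher and 911 lower, where 835 would be expected by chance. That count was 2671 without knockdown clone 1 and 3331 with array weights, and 1088 to 1345 without any 1 of the other clones. Of the 1568, 50 differed at least 2-fold, 32 higher and 18 lower. The 3 knockdown values did not overlap the 3 control values in 2579 genes, or 15.4% of those tested, where chance gives 10%. The count of genes past the threshold depended on single clones: 70 genes passed without knockdown clone 1 (40 higher and 30 lower) and 7 passed without control clone 1 (2 higher and 5 lower). With knockdown clones 2 and 3 averaged as 1 replicate no gene passed. That fit includes clone 1, as does the full fit, which gave 0 too. Without knockdown clone 2 or 3 no gene passed either (smallest adjusted p in limma 0.207 and 0.373). The averaged fit therefore cannot tell the likeness of clones 2 and 3 from the return of clone 1.

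The clones were not equally alike. Across genes, which are not independent replicates, the deviations of knockdown clones 2 and 3 from the control mean correlated at 0.747, while those of clone 1 correlated at 0.20 with clone 2 and at 0.192 with clone 3. Unchanged clones that share the same controls gave 0.251 in a simulation. The covariance of the deviations was 0.0462 for clones 2 and 3, and 0.0122 and 0.0146 for the pairs with clone 1, against 0.00982 in the simulation. The difference from the simulated value estimates what the clones share, and the controls were not split, so part of any excess may come from the shared controls. At least 2-fold differences from the control mean, on the same side, were shared by 70 genes between clones 2 and 3, by 19 between clones 1 and 2, and by 24 between clones 1 and 3. NHSL1 is an example, chosen after its values were seen: its log2 value was 9.75 and 9.48 in knockdown clones 2 and 3, 6.62 in clone 1 and 6.55 on average in the controls, and it passed the threshold without knockdown clone 1.

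**Figure D2:**
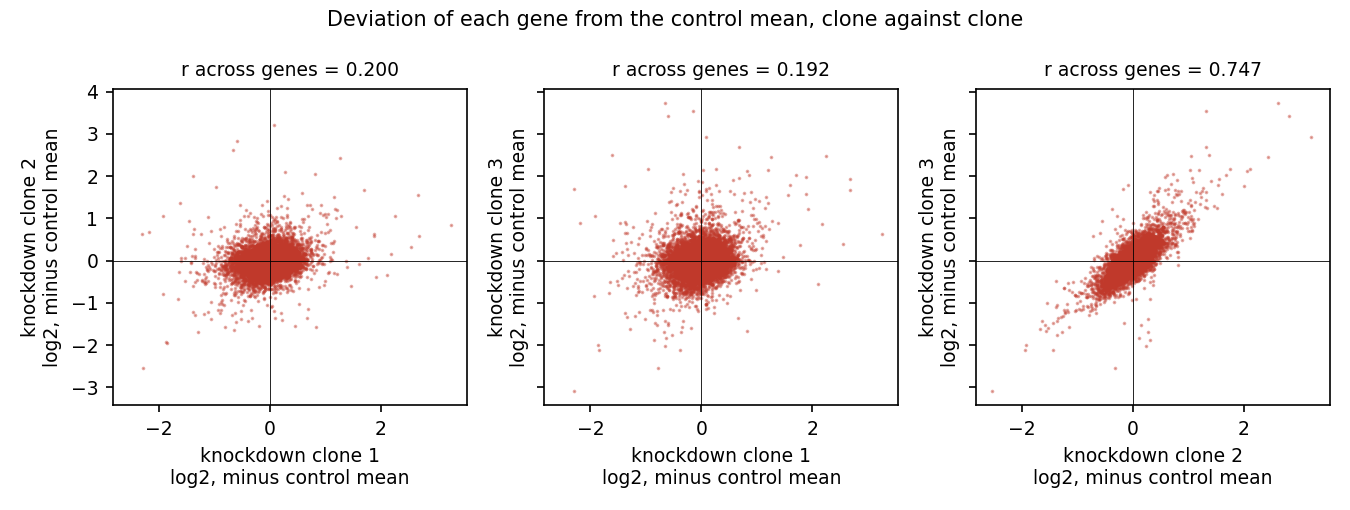
Each point is 1 gene, plotted by its log2 deviation from the mean of the control clones in 1 knockdown clone (horizontal axis) and in another (vertical axis). The cloud is elongated for clones 2 and 3 (r = 0.747) and nearly round for the pairs with clone 1 (0.20 and 0.192).

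With camera's preset correlation the smallest p of all lists was that of cell division. All 37 measured genes of the mitosis and G2/M list had lower means in the knockdown clones, with a median log2 fold change of -0.39, and the list passed camera with its preset correlation (adjusted p = 7.6e-26) but not with an estimated one (adjusted p = 0.503 with an estimated correlation). Over all genes 0 members passed, and 28 passed as lower when adjusted over the list alone. Examples are the kinesin gene KIF11 (-0.53, past the threshold over all genes without knockdown clone 1, adjusted p = 0.0498) and the spindle checkpoint kinase gene TTK (-0.48). The DNA replication and S phase list lay lower as well, with 39 of 40 members lower and a median of -0.26 (adjusted p = 1.6e-09, and adjusted p = 0.62 with an estimated correlation). None of its members passed over all genes, and 0 passed when adjusted over the list alone. MCM6, a subunit of the replicative helicase, had -0.35 and RRM2, of ribonucleotide reductase, had -0.56. By clone, the mean of the mitosis list relative to the control mean was -0.19, -0.45 and -0.58 in knockdown clones 1, 2 and 3. That of the S phase list was 0.04 in knockdown clone 1 and -0.35 and -0.48 in clones 2 and 3, and -0.11 to 0.07 in the controls. The S phase median was -0.41 without knockdown clone 1 and -0.15 without knockdown clone 3.

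**Figure D3:**
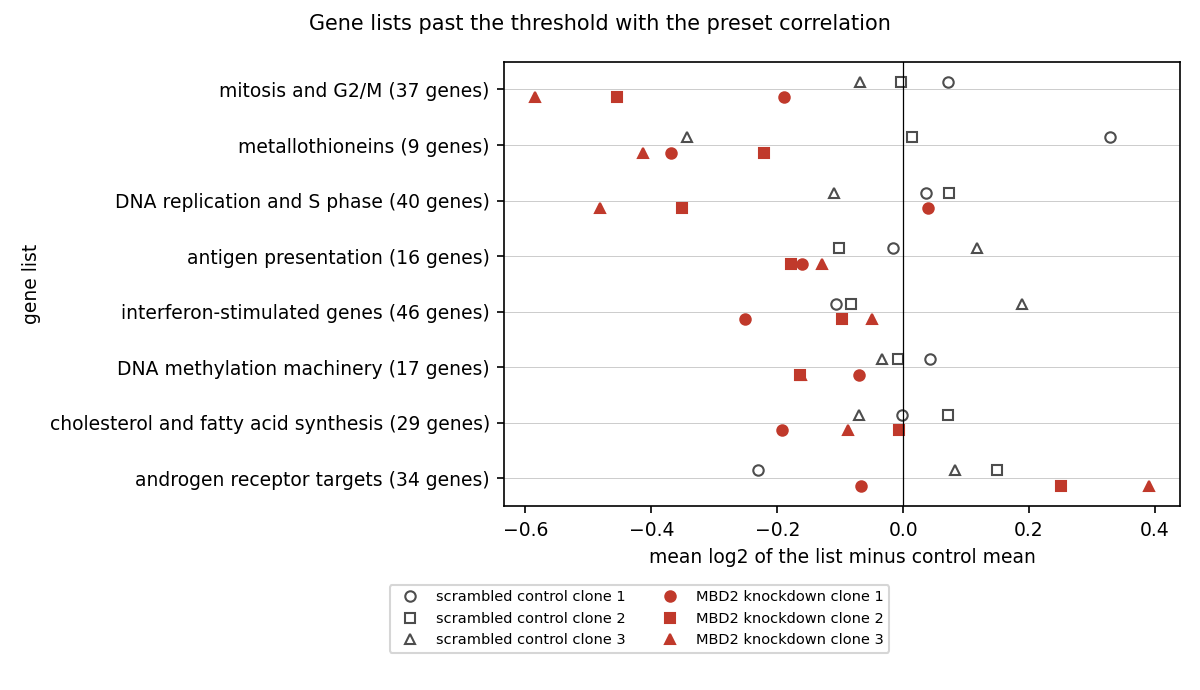
Mean log2 expression of the 8 gene lists that passed camera with its preset correlation, per clone, minus the mean of the control clones; open grey symbols are scrambled control clones and filled red symbols are MBD2 knockdown clones. In the mitosis list the knockdown clones (-0.19, -0.45 and -0.58) lie below every control, and in the S phase list knockdown clone 1 (0.04) lies among the controls.

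The DNA methylation and demethylation machinery list lay slightly lower, with 13 of 17 members lower and a median of -0.11 (adjusted p = 0.0419, and adjusted p = 0.503 with an estimated correlation). Its members with the smallest p were the cytidine deaminase gene APOBEC3B (-0.43) and the dioxygenase gene TET1 (-0.31), and DNMT1, the maintenance methyltransferase, had -0.23. The list's call ended without control clone 1 (adjusted p = 0.122), without knockdown clone 1 (0.132, with a median of -0.064) and without knockdown clone 2 (0.111). The list of the MBD family and NuRD complex had a median of -0.020 over 21 members, a mean of -0.013 and a test direction of higher (adjusted p = 0.937). In it MBD6 had 0.30, and HDAC2, a histone deacetylase of the complex, had -0.24. In neither list did a member pass over all genes or when adjusted over the list alone.

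Lists of genes often silenced by methylation did not pass the threshold. The list of genes hypermethylated in prostate cancer had 18 of 31 members higher and a median of 0.043 (adjusted p = 0.528), which was 0.0019 without knockdown clone 1 and 0.0099 without control clone 3. GSTP1, whose promoter is methylated in most prostate cancers, stood at 5.39 ± 0.10 in the controls and 5.49 ± 0.07 in the knockdown clones (mean ± SD, n = 3 each). KLF6 had -0.32 and GAS6 0.32. The cancer-testis and germline genes had a median of 0.012 over 30 members (adjusted p = 0.877), with 0.49 for MAGEC1 and 0.27 for MAGEA11. The imprinted genes had a median of -0.016 over 18 members (adjusted p = 0.841), with -0.25 for NDN and -0.37 for INPP5F. For the developmental transcription factors with CpG islands, 33 of 46 members were higher with a median of 0.037 (adjusted p = 0.196), and HOXA2 had 0.35 and TBX3 -0.24. That list passed without control clone 3 (median 0.073, adjusted p = 0.0255). The protocadherin list had a median of 0.054 over 15 measured members, all of the beta cluster (adjusted p = 0.328), with 0.25 for PCDHB13 and 0.14 for PCDHB9. Its alpha and gamma members were not measured by features of a single gene. None of the members of these 5 lists passed over all genes, and 0 passed when adjusted over the list alone.

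The antigen presentation list had 13 of 16 members lower and a median of -0.12 (adjusted p = 0.0263, and adjusted p = 0.503 with an estimated correlation). B2M was its 1 member to pass when adjusted over the list alone, and 0 passed over all genes; HLA-DMB had -0.28. This call ended without control clone 1 (adjusted p = 0.0575), control clone 3 (0.0802), knockdown clone 1 (0.154) or knockdown clone 2 (0.0501). Of the interferon-stimulated genes, 30 of 46 were lower with a median of -0.10 (adjusted p = 0.0385, and adjusted p = 0.62 with an estimated correlation). By clone, the mean of the list was -0.25, -0.10 and -0.05 in knockdown clones 1, 2 and 3 and -0.11, -0.08 and 0.19 in control clones 1, 2 and 3, so the groups overlapped. IFIT5 had -0.42, and BST2, which tethers virus particles to the cell surface, had 0.39. IFIT1, IFIT2, IFIT3 and IFIT5 lie in 1 stretch of 13 neighbouring genes with a median of -0.37. The interferon call ended without control clone 3 (median -0.047, adjusted p = 0.454) and without knockdown clone 1 (-0.096, 0.442), and 0 members passed over all genes or when adjusted over the list alone. The haematopoietic markers had a median of 0.036 over 19 members (adjusted p = 0.328), with -0.34 for LCP1 and 0.16 for IKZF1, and none passed over all genes or when adjusted over the list alone.

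Of 34 measured androgen receptor targets 22 were higher, with a median of 0.12 and a mean of 0.19 (adjusted p = 0.0263, and adjusted p = 0.62 with an estimated correlation). TSC22D3, a gene also induced by glucocorticoids, had 1.10, NDRG1 had 0.82 and the kallikrein gene KLK15 had 0.33. With all arrays none passed over all genes or when adjusted over the list alone. The member BMPR1B passed over all genes without control clone 1, as lower. By clone, the mean of the list was -0.07, 0.25 and 0.39 in knockdown clones 1, 2 and 3 and lay between -0.23 and 0.15 in the controls. Its call ended without control clone 1 (median 0.037, adjusted p = 0.742), knockdown clone 2 (0.109, 0.0863) or knockdown clone 3 (0.0087, 0.342), and without control clone 2 the median was 0.189. The luminal epithelial markers had a median of -0.025 over 22 members but a mean of 0.14 and a test direction of higher (adjusted p = 0.657). KRT19, a keratin, had 0.79 and was the 1 member to pass when adjusted over the list alone, and DPP4, a cell-surface peptidase, had 0.88, with 0 passing over all genes.

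Markers of other cell states did not pass. The basal epithelial markers had a median of 0.051 over 18 members (adjusted p = 0.196), with 0.34 for KRT15 and 0.40 for LAMB3. KRT15 is the measured gene next to KRT19, and LAMB3 lies near CD55, with 4 measured genes between them. The neuroendocrine and neuronal genes had a median of 0.050 over 28 members (adjusted p = 0.328), with 0.28 for STMN2 and -0.29 for NEFL. For the mesenchymal transition genes the median was 0.015 over 27 members and the mean -0.0014 (adjusted p = 0.877), with -0.21 for TNC and 0.21 for CALD1. The fibroblast and stromal markers had 15 of 21 members higher and a median of 0.032 (adjusted p = 0.0559), with 0.49 for COL6A1 and 0.23 for COL6A2, which are adjacent genes. That list passed without control clone 1 (adjusted p = 0.0487) and without knockdown clone 3 (0.0322). None of the members of these 4 lists passed over all genes, and 0 passed when adjusted over the list alone.

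Of 9 metallothioneins, small metal-binding proteins, 8 were lower with a median of -0.26 (adjusted p = 0.00501, and adjusted p = 0.62 with an estimated correlation). MT1X had -0.70 and MT2A -0.44. All 9 lie in 1 stretch of 16 neighbouring genes, and the mean of the list was 0.33 in control clone 1 and -0.34 in control clone 3, as low as in the knockdown clones (-0.37, -0.22 and -0.41). Its call ended without control clone 1 (median -0.155, adjusted p = 0.0649) and without knockdown clone 1 (0.127), and 0 members passed over all genes or when adjusted over the list alone. For cholesterol and fatty acid synthesis, 21 of 29 members were lower with a median of -0.095 (adjusted p = 0.0419, and adjusted p = 0.62 with an estimated correlation). ME1, the cytosolic malic enzyme, had -0.67 and was the 1 member to pass when adjusted over the list alone, with 0 over all genes, and CYP51A1 had -0.25. ME1 lies near TTK of the mitosis list, with 7 measured genes between them. By clone, the mean of the list was -0.19, -0.0066 and -0.087 in knockdown clones 1, 2 and 3 and -0.0015, 0.072 and -0.070 in control clones 1, 2 and 3, so the groups overlapped. The call ended without control clone 1 (adjusted p = 0.0575), control clone 2 (0.475, with a median of -0.062) or knockdown clone 1 (0.642, with a median of -0.050).

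The NRF2 targets and glutathione metabolism list moved both ways. Its median was 0.0014 over 31 members, its mean 0.021 and its test direction lower (adjusted p = 0.877). Yet 7 members passed when adjusted over the list alone, 3 higher and 4 lower, with 0 over all genes. Lower were GCLM (-0.56), ME1 (-0.67), NQO1 (-0.59) and MGST1 (-0.33), and higher were the glutathione transferase genes GSTA1 (0.91), GSTM2 (0.80, past the threshold over all genes without knockdown clone 1) and GSTM1 (0.51). Fry's test for change in either direction, which does not compare a list with other genes, gave this list an adjusted p of 0.0147. It also gave 0.0088 for antigen presentation and 0.0457 for cholesterol and fatty acid synthesis.

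Stress and housekeeping groups did not pass. Of the p53 targets and cell cycle inhibitors, 21 of 28 were lower with a median of -0.074 (adjusted p = 0.0825), with -0.49 for PMAIP1 and -1.97 for EDA2R, whose controls ranged from 4.49 to 7.59. That list passed without control clone 1 (median -0.13, adjusted p = 0.00207) and without knockdown clone 3 (-0.094, 0.0322), while without control clone 3 its median was -0.031 (0.448). EDA2R passed without control clone 1 (-2.86, adjusted p = 0.0343). For the unfolded protein and integrated stress response the median was -0.11 over 37 members (adjusted p = 0.193), with -0.56 for DDIT4 and -0.22 for CRELD2. It passed without control clone 3 (median -0.135, adjusted p = 0.0033) and without knockdown clone 1 (-0.178, 0.0453), while its median was -0.034 without knockdown clone 3 (0.870), -0.047 without control clone 1 (0.742) and -0.074 without control clone 2 (0.475). For hypoxia and glycolysis the median was 0.029 over 32 members (adjusted p = 0.377), with 0.82 for NDRG1 and -0.38 for P4HA1. The ribosomal proteins had a median of -0.016 over 34 members (adjusted p = 0.995), with 0.21 for RPS23 and 0.19 for RPL23. The nuclear-encoded oxidative phosphorylation genes had a median of 0.0029 over 38 members and a mean of -0.0025 (adjusted p = 0.897), with -0.22 for NDUFC1 and 0.28 for UQCRB. None of the members of these 5 lists passed over all genes, and 0 passed when adjusted over the list alone.

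In all, 8 of 26 tested lists passed camera with its preset correlation, 1 higher and 7 lower. With an estimated correlation 0 passed, with a smallest adjusted p of 0.503, and fry's directional test also gave 0, with a smallest of 0.177. The DNA methylation and cholesterol lists lost their calls after quantile normalization (medians -0.074 and -0.044, adjusted p = 0.16 and 0.214) and after cyclic loess (medians -0.081 and -0.044, adjusted p = 0.139 and 0.281). Without the dimmest 30% of genes these 2 lost theirs with unchanged medians (0.127 and 0.161), while the median of all genes tested moved from -0.0043 to -0.022. There antigen presentation (median -0.098, 0.0956) and the interferon list (-0.085, 0.45) lost theirs too, and the stromal list gained one (0.0236). Array weights ended the calls of DNA methylation (median -0.060, 0.0936), cholesterol (-0.050, 0.481), antigen presentation (-0.081, 0.0936), interferon (-0.094, 0.323) and metallothioneins (-0.162, 0.107). With knockdown clones 2 and 3 averaged the androgen receptor (median 0.053, 0.132) and DNA methylation lists (-0.116, 0.0607) lost theirs, and the stromal list gained one (0.0419). In simulated data, 37 unchanged genes were given a correlation of 0.6 between members across arrays. Camera's unadjusted p was under 0.05 in 60 of 100 draws with the preset correlation and in 1 of 100 with an estimated one. A list of 37 independent genes shifted lower reached this in 100 of 100 draws with either setting. The estimated correlation was 0.61 for mitosis and 0.71 for S phase, but -0.0036 for antigen presentation and 3.7e-05 for DNA methylation. The simulation of correlated genes does not speak to those last lists. No simulated list was both correlated and shifted. How often the estimated setting would find a true shift in lists like mitosis and S phase was therefore not measured.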

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

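One alternative, averaging knockdown clones 2 and 3 as 1 replicate, was chosen after the arrays had been compared. It gave 0 genes past the threshold, 7 lists (6 shared with the 8 reported) and an MBD2 log2 fold change of -1.30 (adjusted p = 0.378). The 72 other named genes kept their direction in all 1061 comparisons with an alternative, and in 48 of these they passed the threshold. These genes were named by their small p in the same data. In most of them the groups did not overlap, so leaving out an array could not turn their sign. The mitosis and G2/M list and the DNA replication and S phase list passed in every alternative with the preset correlation. With an estimated correlation or with fry's directional test 0 lists passed, and 3 passed fry's test for change in either direction. Without the dimmest 30% of genes 5 lists passed, 4 of them shared. The causes of the shifts below were not tested, except that fewer arrays enter when 1 is left out.

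Genes past the threshold numbered 1, 0 higher and 1 lower (ZNF487), after quantile normalization and after cyclic loess, 325 with array weights (133 higher and 192 lower) and 2 at an adjusted p under 0.1 (1 higher and 1 lower). Leaving out 1 array gave 0 to 70 genes, 0 to 40 higher and 0 to 30 lower, with 70 without knockdown clone 1 and 7 without control clone 1. MBD2 passed with array weights, which gave knockdown clone 1 a weight of 0.252 and clone 2 one of 3.43 (-1.27, adjusted p = 0.0138). Leaving out 1 array gave -1.445 to -1.187, and adjusted p over all alternatives ran from 0.0138 to 0.458. Lists past the threshold numbered 3 with array weights and 4 to 9 with 1 array left out.

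The replicate numbers did not pair the clones: deviations of same-numbered clones correlated at -0.025, -0.19 and 0.17, and only number 3 correlated best with its own number. With the number as a block 0 genes passed (smallest adjusted p = 0.193, 1576 genes at an unadjusted p under 0.05) and 8 lists passed, the 8 reported.

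Medians of lists not past the threshold turned sign as follows. Median centring gave -0.0043 for NRF2 targets and -0.0028 for oxidative phosphorylation. Quantile normalization gave -0.016 for cancer-testis genes, -0.0011 for stromal markers, 0.0096 for imprinted genes, 0.019 for luminal markers, 0.025 for the MBD family, -0.011 for mesenchymal genes and 0.014 for ribosomal proteins. Cyclic loess gave -0.013 for cancer-testis genes, -0.0010 for haematopoietic markers, 0.0059 for imprinted genes, 0.020 for luminal markers, 0.029 for the MBD family, -0.0064 for mesenchymal genes and 0.028 for ribosomal proteins. Without the dimmest genes, basal markers had -3.9e-05, hypermethylated genes -0.0025 and NRF2 targets -0.090. Array weights gave -0.066 for cancer-testis genes, -0.0055 for hypermethylated genes, -0.0076 for haematopoietic markers, 0.053 for luminal markers, -0.015 for mesenchymal genes, -0.0079 for neuroendocrine genes and 0.0090 for ribosomal proteins. Averaging clones 2 and 3 gave -0.012 for cancer-testis genes, 0.0073 for imprinted genes, 0.013 for the MBD family and -0.028 for NRF2 targets.

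With 1 array left out, medians ran from -0.042 to 0.028 (MBD family), -0.036 to 0.011 (NRF2 targets), -0.061 to 0.024 (cancer-testis), -0.0034 to 0.073 (developmental factors), -0.0055 to 0.077 (stromal), -0.026 to 0.080 (haematopoietic), -0.051 to 0.028 (imprinted), -0.047 to 0.055 (luminal), -0.018 to 0.039 (mesenchymal), -0.0020 to 0.088 (neuroendocrine), -0.050 to 0.032 (oxidative phosphorylation), -0.0057 to 0.093 (protocadherins), -0.022 to 0.0090 (ribosomal), 0.0021 to 0.079 (basal), 0.0019 to 0.062 (hypermethylated), 0.0050 to 0.040 (hypoxia), -0.129 to -0.031 (p53), -0.178 to -0.034 (unfolded protein), -0.494 to -0.325 (mitosis), -0.407 to -0.152 (S phase), -0.374 to -0.155 (metallothioneins), -0.156 to -0.101 (antigen presentation), 0.0087 to 0.189 (androgen receptor), -0.132 to -0.047 (interferon), -0.132 to -0.050 (cholesterol) and -0.154 to -0.064 (DNA methylation).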

Other observations

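Chosen only after the result was seen were the tests of MBD2 depth between clones, of the gap in the S phase list and of the splits for genes past the threshold, and the added demand that a shared origin keep neighbouring genes within the shuffles, as well as the genes and stretches named in this part.

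Relative to the control mean, 7 genes were at least 2-fold higher and 8 at least 2-fold lower in all 3 knockdown clones, against 155 and 125 in any of them. The higher ones included PLOD2, a collagen lysyl hydroxylase (log2 fold change 2.05), ACOX2, a peroxisomal enzyme of bile acid synthesis (2.05), CAMK2N1, an inhibitor of CaM kinase (1.92), the glutamate receptor gene GRIN3A (1.51) and ASS1, which makes argininosuccinate (1.30). The lower ones included COLCA1 (-2.64), the ectodysplasin receptor EDA2R (-1.97), BRINP1 (-1.93), LXN (-1.53), TMEM45B (-1.32) and FRAS1 (-1.18). None passed the threshold in limma with all arrays. Without control clone 1 BRINP1, FRAS1, ASS1 and EDA2R passed, without knockdown clone 1 ACOX2 did, and array weights brought ACOX2, BRINP1 and FRAS1 past it. In LXN the controls themselves ranged from 2.76 to 6.01. COLCA1 lies near EXPH5 and ZC3H12C, with 6 and 3 measured genes between. Single control clones differed 2-fold too. Against the mean of 2 control clones, control clones 1, 2 and 3 had 27, 27 and 55 genes higher and 65, 14 and 21 lower. Knockdown clones 1, 2 and 3 had on average 47.7, 57 and 126 higher and 79.7, 44 and 58 lower.

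Some differences covered stretches of neighbouring genes. In 5 stretches the median log2 fold change of 11 adjacent measured genes went beyond the highest of 100 shuffles of gene order. Single clones gave such stretches too: 9, 2 and 6 in knockdown clones 1, 2 and 3 against the control mean, and 0, 3 and 7 in control clones 1, 2 and 3 against the other controls. PLA2G4A to CFHR2 (15 genes) lay higher with a median of 0.21 over the whole stretch. Lower were H2AC12 to ZSCAN16 (19 genes, -0.19), which holds histone genes, LIPA to PCGF5 (13 genes, -0.37), MT3 to CETP (16 genes, -0.31) and ZNF738 to ZNF726 (12 genes, -0.29), which holds zinc finger genes. The medians of MT3 to CETP were 0.28, 0.03 and -0.24 in control clones 1, 2 and 3, and those of ZNF738 to ZNF726 were -0.02, -0.24 and 0.39. The linker histone gene H1-5 had -1.17, with 8.89, 8.05 and 8.04 in knockdown clones 1, 2 and 3 and a mean of 9.50 in the controls, and passed without knockdown clone 1.

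The log2 fold changes of adjacent genes correlated at 0.164 across 16646 pairs, where the highest of 1000 shuffles was 0.0248. Sequence shared within gene families is argued against as the whole cause of this correlation over all pairs. Without pairs whose symbols share 3 letters it was 0.1395 (highest shuffle 0.0261). The stretches named above were not retested without such pairs, so for them shared sequence stays open. A correlation of adjacent genes also appeared between clones of 1 group: in the differences of 1 control clone from the others it was 0.1363 at its lowest. Changes of chromosome regions in single clones, such as in copy number, may therefore account for part of the pattern, and shared regulation of neighbours stays open. The knockdown itself as a biological cause was not tested.

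Knockdown clones 2 and 3 deviated together and clone 1 apart from them. The narrower distribution on the array of clone 1 is argued against. After quantile normalization the correlation of clones 1 and 2 stayed at 0.189, against 0.745 for clones 2 and 3. That step only evens out the distributions, so other faults of that array were not tested and stay open. A shallower knockdown is argued against at the level of RNA, the only level measured here. MBD2 RNA in clone 1 was lower than the mean of clones 2 and 3 (difference -0.1436). Whether clones 2 and 3 share an origin stays open: in their difference the covariance of adjacent genes was 0.001811 (correlation 0.0665), against 0.00489 to 0.00758 (0.133 to 0.164) between control clones, but it was above the highest shuffle (0.000625), and a covariance shrinks with the size of the difference, for which this pair was singled out. With both averaged 0 genes passed, but that fit includes clone 1, as does the full fit with 0, so it does not bear on origin. A different response of clone 1 to the loss of MBD2 stays open, as untested.

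The mitosis list lay lower in all 3 knockdown clones and the S phase list in clones 2 and 3. After quantile normalization the median of the mitosis list was -0.3429, or 0.874 of its value before, and that of the S phase list was -0.21. The mitosis median rests mostly on clones 2 and 3 (means -0.45 and -0.58, against -0.19 in clone 1). The test therefore cannot tell whether the narrower distribution on the array of clone 1 made that clone's own value. Without knockdown clone 1 the mitosis list still passed with the preset correlation, so the lower values of clones 2 and 3 do not rest on that array. The growth state of single clones cannot be told apart from an effect of the knockdown for mitosis: the gap of 0.1216 between the lowest control and the highest knockdown clone was smaller than the range of 0.395 among knockdown clones, though 25 of 37 members did not overlap. For S phase the gap was -0.1489, since clone 1 lay among the controls, and this is consistent with a state of clones 2 and 3. An effect of MBD2 on proliferation stays open as a biological explanation.

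With 10 splits of the 6 arrays a share under 0.05 cannot be reached. The real split gave 0 genes past the threshold and the highest other gave 1; since no count lies under 0, that 10 of the 10 gave as many was fixed beforehand and says nothing about chance. At an unadjusted p under 0.05 the real split gave 1568 genes and the highest other 1699, with control clone 3 and knockdown clones 2 and 3 on one side. For lists the real split gave 8 and the highest other 8, and as many came from 2 of the 10 splits in both counts.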
